A study of Homo sapiens with 8 samples.

How the data were processed

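RNA was measured by sequencing in pneumospheres, floating spheres grown from non-small cell lung cancer lines in ultra-low attachment flasks with serum-free medium and growth factors. There were 8 libraries from 4 established lines. Per the labels, H23, H820 and H1975 are adenocarcinoma and EBC1 is squamous cell carcinoma. Each line gave 1 untreated library and 1 library of spheres given PD-L1s, a synthetic soluble form of the immune checkpoint ligand PD-L1, at 25 µg/ml for 15 min in medium without serum. Per the labels' protocols, RNA was extracted on a Maxwell RSC instrument and total RNA libraries were made with a strand-preserving Illumina kit that removes ribosomal RNA. Such libraries hold unspliced and noncoding RNA as well as messenger RNA.

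The deposited values are raw counts of read pairs per gene, not normalised. Per the submitters' processing notes, reads were aligned to GRCh37 (hg19) with STAR 2.7.3a and counted with featureCounts of Subread 2.0.0. Per the file headers, exons were summed per gene of the GENCODE basic annotation lifted to GRCh37, in the reverse-stranded setting. Only primary alignments with both ends aligned and a mapping quality of at least 1 were counted. A pair overlapping several genes on the same strand was counted for each of them, so overlapping genes share reads. The files also give the exonic length of each gene, which was not used in a test. Primary alignments of pairs that fit several near-identical genes can fall on any copy, so counts of such copies are uncertain. Genes on opposite strands were counted apart. The files hold 60106 genes. Coordinates are those of the files, GRCh37, counted from 1. Transcript sequences of a later annotation, matched by gene identifier, were used only for GC content and for a search of near-identical copies.

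Total counts ran from 5559870 to 27524854 per library. The untreated and treated libraries held 20310707 and 15563010 counts in H23 and 23751862 and 22241208 in H1975. Depth was uneven in the other lines, with 5894946 and 27524854 counts in EBC1 and 5559870 and 23783679 in H820. A gene with 0 counts may still have had up to 3 counts' worth of RNA in the libraries concerned, and bounds computed from that floor, on the TMM scale, cover counting error only.

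Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, in R 4.3.3) on the deposited counts, with TMM scaling and cell line plus treatment as the terms, so that each line served as its own control. The 4 lines were the replicates of the treatment. The same-line pairing comes from the labels. Genes were kept by edgeR's expression filter with a minimum count of 10 and the line as the group, which left 24185 genes. P-values were adjusted over all genes tested by the Benjamini-Hochberg method and called under 0.05. The same fit gave the contrast of EBC1 with the mean of the other lines and of each other line with the mean of the rest. These contrasts rest on 2 libraries per line, so their p-values measure the spread between libraries of a line and not between tumours. The difference in response between EBC1 and the adenocarcinoma lines was tested as an interaction term, in which EBC1 gave a single pair and the spread came from the other 3 lines. Within a line there was 1 library per condition and no replicate check. There, log2 ratios of CPM (counts scaled to the TMM-adjusted library total) were formed with a prior count of 5, and genes with at least 50 counts in a library were described by a change of over 2-fold. Levels are given in TMM-scaled CPM. All tests were two-sided.

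Before the data were examined, 39 gene lists were fixed from textbook knowledge. They covered signalling responses, the cell cycle, metabolism, stress, lineage and state of lung tumour cells, RNA classes, and markers of other cell types. Of their 739 symbols, 737 were matched in the files. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated from the data, and fry, were alternatives. For each list, members were also counted with p-values adjusted over the list alone. Within lines, the median log2 ratio of a list was ranked among 10000 random lists of the same size and similar expression. The consistency of the immediate early list over lines was tested by an exact sign-flip test.

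The genes named were chosen by a rule written before the data were examined. For the treatment it took up to 10 genes per direction with the largest change among those past the threshold and moving the same way in every line. Free places were filled by the smallest unadjusted p among genes moving the same way in every line, with an average log2 CPM of at least 1. CD274, PDCD1, MET, EGFR, FOS and EGR1 were always named. The rule took up to 4 members of each list by unadjusted p, and the 3 largest rises and falls within each line. For EBC1 it took the 10 highest and 10 lowest called genes, and for each other line the 5 highest and 5 lowest, with an average log2 CPM of at least 3. Some genes the rule took for EBC1 and H820 are not reported. It was limited to protein-coding genes, except for members of lists. Genes named outside the rule are marked as chosen after their values were seen.

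The procedure was tested on simulated counts with the real means and library sizes. In the treatment comparison over 24185 genes, 39 of 67 genes changed 1.5-fold were called (58.2%), 62 of 67 changed 2-fold (92.5%) and 66 of 66 changed 4-fold, with 9 false calls among 176. With nothing changed there was 1 call. In the contrast of EBC1, 188 of 200 changed genes were recovered with 16 false calls. The immediate early list, raised 1.5-fold in all lines, was called together with 1 other list, which may share members with it. Genes were drawn independently and changed alike in every line. The simulations therefore cannot test the list calls where genes are correlated or where lines differ.

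Alternatives tried were scaling by the median-ratio method (RLE) or by library size only, no filter on low counts, a minimum count of 50, protein-coding genes only, counts thinned to the smallest library, DESeq2 1.42.0, limma-voom, no pairing by line, and leaving out each line or library in turn. Chosen after seeing the data were a GC correction, since the EBC1 pair showed a GC trend, and a fit of H23 and H1975 only, the lines whose libraries had similar depth. GC content was known for 97.8% of the genes tested. No library was left out of the main comparisons.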

Results

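The series measured RNA in spheres of 4 non-small cell lung cancer lines, untreated (n = 4 libraries) or given soluble PD-L1 for 15 min (n = 4). Each library lay nearest to the other library of its own line, with a Pearson r across genes of 0.979 to 0.995 against at most 0.883 with a library of another line. Sequencing depth was similar within the pairs of H23 and H1975, but the treated libraries of EBC1 and H820 were 4.67 and 4.28 times as deep as their untreated partners. CD274, the gene for PD-L1, had 24.4 CPM in untreated and 45.3 CPM in treated H820, 12.7 and 12.8 in EBC1, 9.30 and 11.8 in H1975, and at most 0.201 in H23. PDCD1, the gene for its receptor PD-1, had 0 to 4 counts per library and was below the filter.

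The comparison of treated with untreated spheres asks which transcripts differ 15 min after PD-L1s was added. FOSB and FOS were higher in every line. FOSB, a subunit of the AP-1 transcription factor induced within minutes by growth signals, was 6.28-fold higher (log2 2.65 ± 0.193, SE, n = 4 lines, adjusted p = 1.54e-06). It went from 25.9 to 224 CPM in H23, 51.9 to 159 in EBC1, 12.9 to 111 in H820 and 3.62 to 26.2 in H1975. FOS, another AP-1 subunit of the same family, was 4.55-fold higher (log2 2.19 ± 0.218, adjusted p = 1.15e-04), going from 45.5 to 209, 54.0 to 120, 14.6 to 157 and 18 to 81 CPM in the same order. DUSP1, a phosphatase that switches MAP kinases off, was 2.04-fold higher (log2 1.03 ± 0.151, adjusted p = 8.55e-03), and CYR61, a secreted matrix protein and YAP target, 1.88-fold higher (log2 0.91 ± 0.143, adjusted p = 1.48e-02). Both were higher in 4 of 4 lines. DUSP1 and CYR61 lost their call at a minimum count of 50 (adjusted p = 0.105 and 0.123), without EBC1 (0.117 and 0.0947) and without the pairing by line. CYR61 also lost it with protein-coding genes only (adjusted p = 0.0554) and limma-voom (0.0624). The genes lie at chromosome 19 from 45971253 to 45978437 for FOSB (ENSG00000125740.13_3), chromosome 14 from 75745477 to 75748933 for FOS (ENSG00000170345.9_3), chromosome 5 from 172195093 to 172198198 for DUSP1 (ENSG00000120129.5_2) and chromosome 1 from 86046444 to 86049645 for CYR61 (ENSG00000142871.16_3). All are protein-coding, and the values are counts over their exons.

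In all, 9 of 24185 genes passed, 7 higher and 2 lower, and 873 had an unadjusted p under 0.05. RP11-1212A22.4, a transcript of the NPIP family of near-identical genes on chromosome 16 (18451943 to 18473188, ENSG00000233024.3), was 4.26-fold higher (log2 2.09 ± 0.216, adjusted p = 1.32e-04) and higher in each line. Its best match among other genes was 100% identical over the transcript, so its count is uncertain. The remaining 4 calls rested on H820 and were lost at a minimum count of 50. HHLA2, a B7 family checkpoint ligand, went from 61.3 to 169 CPM there (adjusted p = 8.07e-03) and FGB, the fibrinogen beta chain, from 19.0 to 147 (adjusted p = 1.05e-02). CEACAM5, the carcinoembryonic antigen, went from 250 to 41.6 CPM (adjusted p = 8.07e-03). AC011513.3, which overlaps CEACAM5 and shares its reads, went from 51.5 to 8.92. Under DESeq2 the fitted change of FGB and of CEACAM5 turned, to log2 -1.08 and 1.07.

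EGR1, a zinc finger transcription factor of the same early response, had log2 1.48 ± 0.261 and did not pass (adjusted p = 0.0535), with 1.15 in H23, 0.55 in EBC1, 3.22 in H820 and 1.27 in H1975. It passed when H23, H820 or H1975 was left out, and with H23 and H1975 only. CTGF, a matrix protein under YAP, had 1.21 ± 0.283 (adjusted p = 0.650), the choline transporter gene SLC44A4 1.09, NR4A1, a nuclear receptor of the early response, 0.61 and PPP1R15A, a stress-induced phosphatase subunit, 0.51. No gene moving down in every line passed. The fitted log2 values of the first of these by p were -0.89 for the interferon gene IFNE, -0.68 for CUZD1, -0.57 for ANKDD1B, -0.54 for MAFA, -0.48 for MNX1, -0.44 for TAS2R4, -0.42 for CCDC136, -0.38 for ZNF789, and -0.34 for CLN8 and SLC36A1. CD274 had 0.42 ± 0.170, MET, the receptor for hepatocyte growth factor, 0.22 ± 0.147 and EGFR 0.12 ± 0.114, none passing. With a line left out in turn, 5 (without EBC1) to 20 (without H23) genes passed, and 19 without H1975. Without the pairing by line none did.

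**Figure D1:**
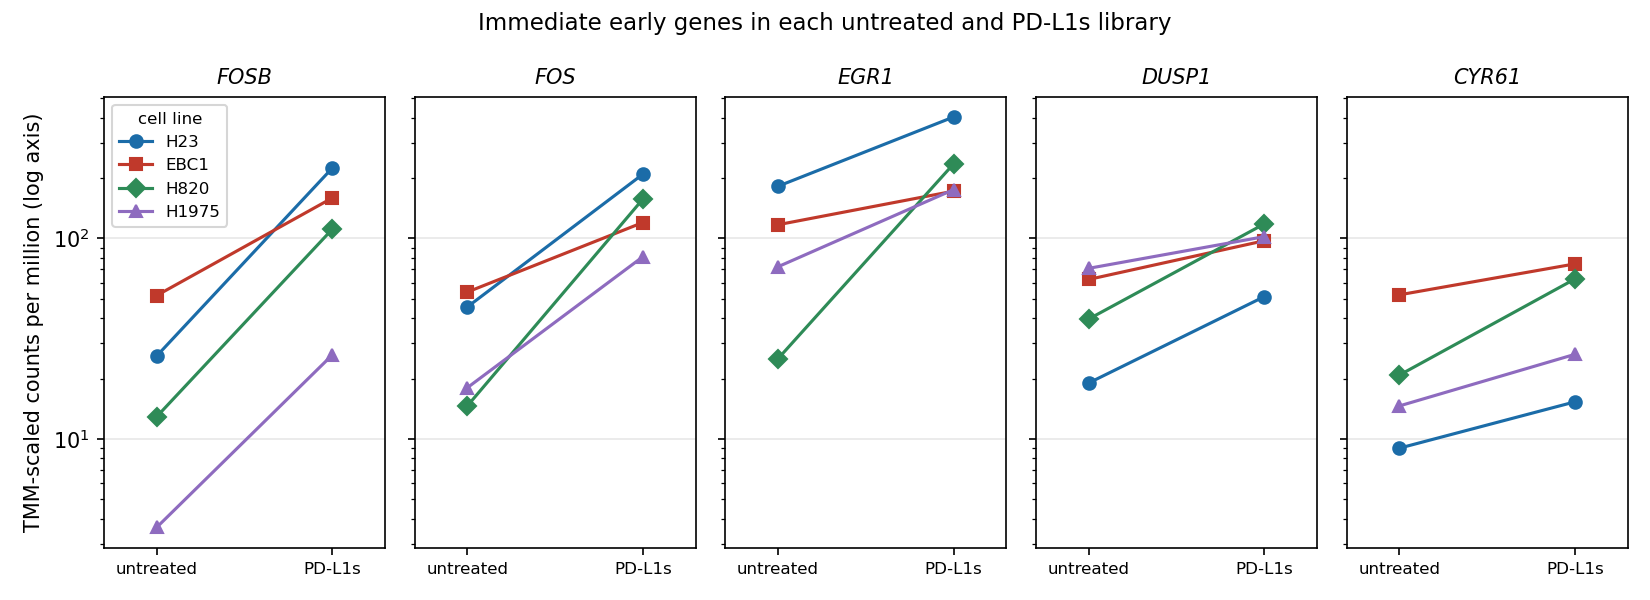
TMM-scaled CPM (log axis) of FOSB, FOS, EGR1, DUSP1 and CYR61 in the untreated and PD-L1s library of each line, joined by a line per cell line. All 4 lines slope upward for each gene, FOSB in H820 from 12.9 to 111 and FOS in H820 from 14.6 to 157; EGR1 did not pass the test.

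All 37 members of the list of immediate early response genes, which are transcribed from factors already present in the cell, had positive fitted changes (median log2 0.37). 4 of them passed over all genes and 21 passed higher when adjusted over the list alone. Beside those above, KLF2 had 0.89, DUSP2 0.82, JUNB 0.59, JUN 0.58, NR4A2 0.47, KLF4 0.39, MCL1 and MYC 0.35, ATF3 0.29 and ARC 0.00, none passing over all genes. The list was called higher (adjusted p = 1.14e-26), but not with a correlation estimated from these 8 libraries (adjusted p = 0.60 with an estimated correlation). Its median log2 ratio within a line was 0.19 in H23, 0.30 in EBC1, 0.62 in H820 and 0.20 in H1975, at or above the 99.99 percentile of random lists in each. Such percentiles treat the genes of 1 pair as independent, and other lists reached them in single lines. The histone, G2/M and hypoxia lists were at 100 in H820, and mitochondrial genes at 100 in H1975. Over lines the mean of the immediate early medians was 0.33 (SD 0.202, n = 4), and the exact sign-flip test gave p = 0.125, the smallest that 4 lines can give. With H23 and H1975 only, a fit chosen after seeing the data, the median was 0.21 and 10 members passed.

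Of the 39 lists, 23 were called, 21 higher and 2 lower, and none kept its call with an estimated correlation (adjusted p from 0.60 to 0.990 over the lists) or with fry. Without H820, 12 were called, 11 of them among the 23. The YAP/TAZ targets (17 tested, median 0.22, adjusted p = 2.22e-08, 0.60 with an estimated correlation) held CYR61, CTGF, AMOTL2 and F3, with 1 member past the threshold over all genes and 3 adjusted over the list alone. Their median was 0.80 in H820, 0.30 in EBC1, 0.01 in H23 and 0.04 in H1975, and 0.14 without H820 (adjusted p = 3.26e-04). CYR61 and CTGF are also members of the immediate early list, as is JUNB, which is among the JAK-STAT targets. CTGF is among the TGF-beta targets too, so the calls of these lists are not independent. The genes of the mitochondrial genome, 13 of 13 below 0, had a median of -0.33 (adjusted p = 2.26e-10, 0.60 with an estimated correlation), with 0 passing over all genes and 6 lower adjusted over the list alone. Their median was -0.75 in EBC1 and -0.68 in H820, the lines with uneven depth, and -0.15 in H23 and 0.17 in H1975. The mitochondrial share of counts went from 1.65 to 0.97% in EBC1 and from 4.07 to 2.47% in H820, against 2.01 to 2.07% in H23 and 2.34 to 2.56% in H1975. NRF2 targets, the antioxidant genes, were the other list called lower (median -0.10, adjusted p = 9.84e-04, 0.60 with an estimated correlation). Their median was -0.44 in H820, -0.12 in H23, 0.17 in EBC1 and 0.03 in H1975, and -0.01 without H820 (adjusted p = 0.725).

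Lists of cycling and hypoxic cells were called higher, with H820 setting their size. G2/M genes such as CDK1, BUB1, TOP2A and KIF11 had a median of 0.39 (22 of 22 above 0, adjusted p = 2.22e-08), made of -0.07 in H23, 0.09 in EBC1, 1.94 in H820 and 0.04 in H1975. Without H820 the median was 0.01 (adjusted p = 0.751). Hypoxia response genes such as ANGPTL4, PFKFB4 and ADM had 0.27 (adjusted p = 5.44e-07), made of -0.09, 0.16, 1.06 and 0.00, and 0.01 without H820 (adjusted p = 0.491). Replication-dependent histone genes had 0.35 (adjusted p = 1.45e-09), with 8 higher adjusted over the list alone, and G1/S genes 0.26 (adjusted p = 1.53e-07). The histone median was 0.09 in H23, 0.26 in EBC1, 1.13 in H820 and 0.12 in H1975. Without H820 camera still called histone genes (median 0.15, adjusted p = 1.61e-04) and G1/S genes (0.08, 0.03). With an estimated correlation the G2/M, hypoxia, histone and G1/S lists each had adjusted p = 0.60.

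The other lists called higher by camera were antigen presentation genes (median 0.24, adjusted p = 2.86e-06), JAK-STAT targets (0.32, 3.49e-06), NF-kB targets (0.22, 4.89e-06), cholesterol synthesis and SREBP targets (0.18, 1.20e-04) and epithelial state genes (0.22, 1.80e-04), each lost (adjusted p = 0.60 with an estimated correlation). Glycolysis enzymes (0.14, adjusted p = 1.81e-03), endoplasmic reticulum chaperones (0.15, 2.47e-03), TGF-beta targets (0.09, 5.85e-03), FOXO targets (0.19, 8.88e-03) and nuclear-encoded respiratory chain genes (0.10, 9.53e-03) followed, all lost too (adjusted p = 0.60 to 0.623 with an estimated correlation). Receptor tyrosine kinases and ligands (0.17, adjusted p = 0.0157), ribosomal protein genes (0.09, 0.0222), the immune checkpoint axis (0.14, 0.0222), alveolar lineage genes (0.23, 0.0299) and Notch pathway genes (0.17, 0.0484) were nearest the threshold, and also lost (adjusted p = 0.60 to 0.710 with an estimated correlation). Without H820 the medians were 0.11 for antigen presentation (adjusted p = 0.03), 0.13 for JAK-STAT (0.03) and 0.10 for NF-kB (5.16e-04). In H23, EBC1, H820 and H1975 they were -0.06, 0.31, 0.65 and 0.06 for antigen presentation, -0.04, 0.50, 0.97 and -0.05 for JAK-STAT, and 0.00, 0.15, 0.44 and 0.10 for NF-kB. The calls without H820 of glycolysis enzymes (median 0.04, adjusted p = 0.595), chaperones (0.02, 0.815), FOXO targets (0.04, 0.556) and nuclear-encoded respiratory chain genes (0.03, 0.842) were lost. So were those of cholesterol (adjusted p = 0.130) and epithelial (0.058) genes, ribosomal proteins (0.210), the checkpoint axis (0.263) and alveolar genes (0.369). With H23 and H1975 only, glycolysis enzymes, nuclear-encoded respiratory chain genes and ribosomal proteins were called lower, the reverse of the main call. Not called in the main comparison were small structured RNAs (adjusted p = 0.0675), p53 targets (0.0869), mesenchymal state genes (0.200), fibroblast markers (0.275), interferon-stimulated genes (0.30) and neuroendocrine genes (0.440). The same held for stem cell and sphere markers, endothelial markers and Wnt targets (adjusted p = 0.647 each), the integrated stress response (0.650), and Hedgehog and MAPK feedback genes (0.652 each). Markers of immune cells (adjusted p = 0.699), nuclear long noncoding RNAs and heat shock genes (0.783 each) and squamous lineage genes (0.989) were furthest from a call.

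**Figure D2:**
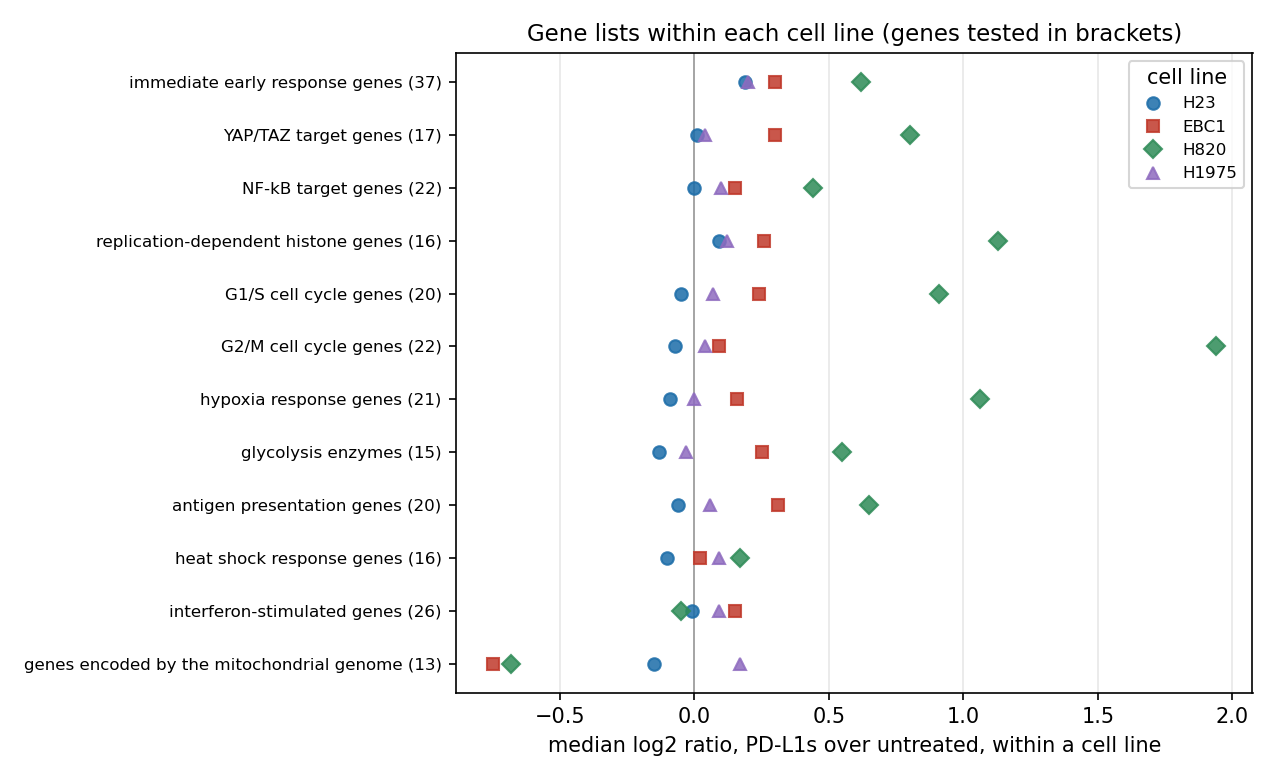
Median log2 ratio (PD-L1s over untreated) of the tested members of 12 gene lists within each cell line; each marker is the median of a list in a line and the number of genes tested is in brackets. The median of immediate early genes lies above 0 in all 4 lines (0.19 to 0.62), while G2/M genes reach 1.94 and hypoxia genes 1.06 in H820 and lie between -0.09 and 0.16 in the other lines.

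Within single lines, described without a test, H820 changed most and H1975 least. Of 14883 genes with enough counts in H820, 631 were over 2-fold higher and 129 over 2-fold lower, against 186 and 16 of 13967 in EBC1, 22 and 14 of 15447 in H23, and 20 and 4 of 15049 in H1975. With library size only, the median of all genes in H820 moved by -0.17 and the counts there were 387 and 321. Among protein-coding genes, the largest rises in H820 were those of ANKRD37, a hypoxia-induced gene (log2 ratio 3.49, 44 to 1862 counts), FOS (3.41) and PPP1R3C, a glycogen-targeting phosphatase subunit (3.34). The largest decreases in this class were those of CYP1A1, a target of the aryl hydrocarbon receptor (-5.13, 133 to 8 counts), the hemoglobin gene HBA2 (-3.75, 72 to 14) and CEACAM7 (-2.70). Among protein-coding genes of H23, FOSB (3.10), FOS (2.19) and RP11-1212A22.4 (1.60) led, and NPIPB11 (-2.43), AC127496.1 (-0.94) and UQCRHL (-0.91) were lowest. Among those of EBC1, RP11-1212A22.4 (2.30), C4orf48 (1.82) and the histone gene HIST2H3D (1.71) led, and the mitochondrial gene MT-ND5 (-1.35), CCDC146 (-1.23) and WBP2NL (-1.12) were lowest. Among those of H1975, the keratin genes KRT6A (2 to 119 counts) and KRT1 (0 to 89) and the skin gene S100A7A (0 to 50) led, and ANXA8L1 (-1.31), NPIPB5 (-0.97) and MAP1LC3A (-0.95) were lowest. NPIPB11 and NPIPB5 belong to families of near-identical genes and are uncertain.

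Across all 24185 genes the responses of different lines were nearly unrelated. The Pearson r of log2 ratios across genes, which are not independent replicates, was 0.079 for EBC1 with H820, 0.030 for H820 with H1975, 0.012 for H23 with EBC1, -0.001 for H23 with H820, -0.002 for H23 with H1975 and -0.049 for EBC1 with H1975. Among 6438 highly expressed genes the range was -0.225 to 0.124.

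EBC1 was compared with the adenocarcinoma lines to describe how the line labelled squamous differs. EBC1 carried high levels of MET, the receptor for hepatocyte growth factor, at 6790 and 7610 CPM in its untreated and treated library, against 59.9 to 1710 in the others (log2 4.35 ± 0.154, SE, adjusted p = 1.09e-13). Among the highest genes were CDH2, the neural cadherin (mean 125 CPM against 0.872 in the other 6 libraries), NOG, an inhibitor of bone morphogenetic proteins (240 against 1.42), HLA-DQB1, a class II antigen-presenting molecule (263 against 0.674), and the mucin MUC4 (443 against 2.78). LCP1, an actin-bundling protein (441 against 7.28), HIST1H3C (71.2 against 5.18), EDN2 (43.9 against 0.670), SFMBT2 (34.3 against 2.78) and TMEM71 (34.2 against 1.09) were also among them. The 10 lowest had 0 counts in both EBC1 libraries. Against a floor of 3 counts over the pair, PLXNB2, a semaphorin receptor, was at least 3590-fold lower, the tumour antigen gene PRAME at least 709-fold, the death-associated kinase gene DAPK1 661-fold, PPP6R2 465-fold and RP1-34B20.21, which overlaps HIST1H3D and shares its reads, 448-fold. HIST1H3G (321-fold), the interleukin receptor gene IL17RA (315-fold), HIST1H4E (281-fold), HIST1H2AD (280-fold) and RNF212 (226-fold) followed.

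In this contrast 13167 of 24185 genes passed, 6791 higher and 6376 lower. The split depended on scaling, since with library size only the median of all genes moved by -0.32 on the log2 scale and 4779 were higher and 8923 lower. Without the treated EBC1 library 8691 genes passed. CD274 was higher by log2 1.66 ± 0.225 (adjusted p = 4.99e-06), with H820 above EBC1 and H23 near 0. The squamous lineage list went both ways, 5 higher and 5 lower of 14 (adjusted p = 0.821), as did alveolar genes, 5 and 4 of 14 (adjusted p = 0.805). TP63, the regulator of squamous fate, had 0.192 and 0.314 CPM in EBC1 but 87.2 and 86.7 in H1975. NKX2-1, the regulator of alveolar fate, had 0 and 0.224 CPM in EBC1, 35.6 and 54.0 in H820 and 78.4 and 75.2 in H1975.

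Of the gene lists 14 were called in EBC1, 13 higher and 1 lower, and none with an estimated correlation (adjusted p = 0.723 with an estimated correlation, for each). Cholesterol synthesis and SREBP targets were higher in 21 of 21 members (median log2 2.12, adjusted p = 1.61e-10), such as FDFT1, squalene synthase (3.16), MSMO1 (2.94) and DHCR7, the last enzyme of the pathway (2.65). Epithelial state genes were higher in 20 of 22 (median 2.02, adjusted p = 2.36e-08). Set against the mean of the rest in the same way, the list had 2.18 in H1975, 1.65 in H820 and -6.15 in H23. H23 is part of the mean that EBC1 was set against, so its low levels raised the EBC1 value. CDH1, the epithelial cadherin, had 1130 and 1290 CPM in EBC1, 332 to 860 in H820 and H1975, and at most 2.01 in H23. Antigen presentation genes were higher in 17 of 20 (median 1.56, adjusted p = 2.63e-07), with the class II gene CD74 at 378 and 466 CPM against 0 to 156 and HLA-DRB1 at 35.2 and 53.2 against 0.503 to 8.18. NF-kB targets (15 higher of 22, adjusted p = 1.54e-04) held the chemokines CXCL3 (log2 4.86), CXCL1 (2.93) and CXCL8 (2.64), of which CXCL1 had 171 and 183 CPM in EBC1 and 165 and 184 in H820. The NF-kB median was 1.10 in EBC1 but 1.56 in H820, 0.22 in H1975 and -2.99 in H23, each against the mean of the rest. Antigen presentation and hypoxia lists were low in H23 too (median -2.54 and -1.49). NRF2 targets (15 of 18, adjusted p = 1.54e-04), G1/S genes (19 of 20, 9.06e-05), hypoxia genes (16 of 21, 2.44e-04), ribosomal proteins (24 of 32, 6.82e-06), glycolysis enzymes (12 of 15, 8.29e-04), small structured RNAs (13 of 14, 1.53e-03), endoplasmic reticulum chaperones (11 of 17, 3.67e-03) and YAP targets (9 of 17, 9.01e-03) were also higher. Immediate early genes went both ways, 19 higher and 9 lower of 37, and the list was called higher (adjusted p = 0.0373), with the AP-1 gene FOSL1 at log2 4.24. Mitochondrial genes were lower in 11 of 13 (median -0.92, adjusted p = 0.0131).

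**Figure D3:**
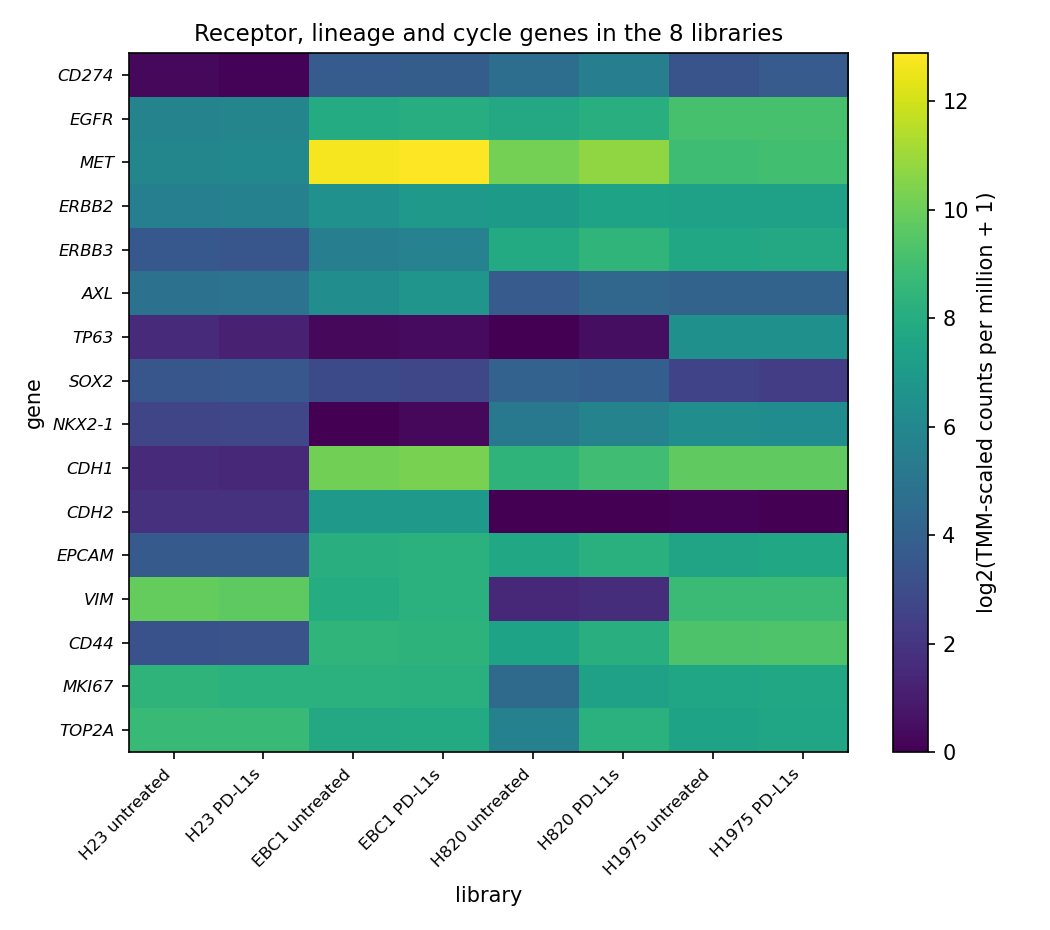
Levels of 16 receptor, lineage and cell cycle genes (vertical) in the 8 libraries (horizontal), coloured by log2 of TMM-scaled CPM plus 1. MET is brightest in EBC1 (6790 and 7610 CPM), TP63 in H1975 (87.2 and 86.7 CPM), and CDH1 is dark in H23 (at most 2.01 CPM).

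Each adenocarcinoma line also differed from the rest, by 14940 genes in H23 (8322 higher, 6618 lower), 12942 in H820 (7393 and 5549) and 12955 in H1975 (7486 and 5469). With library size only the median of all genes for H23 moved by 0.44 on the log2 scale and the split was 12171 higher and 4300 lower. The highest genes of H23 included neuronal ones. RORB, a nuclear receptor of neurons, had 178 CPM and 0 counts elsewhere (at least 5880-fold higher), NTS, the neurotensin gene, was at least 2960-fold and ATCAY at least 2370-fold higher, and CHGB, a secretory granule protein, had 403 CPM against 0.116. PDE3A had 133 CPM against 0.00774, a single count. H23 had no counts of SLC43A3 (at least 665-fold lower), HLA-DRA (564-fold), DAPP1 (534-fold), the kinase gene SYK (524-fold) and TCN1 (353-fold). H820 was high in DUOXA2, a maturation factor of a peroxide-producing oxidase (402 CPM against 0.0476), and in CTB-16J4.1 (at least 2830-fold), and had no counts of NOG (at least 745-fold lower), KLRC4-KLRK1 (223-fold), THNSL2 (208-fold), the myosin light chain gene MYL9 (130-fold) and SULF2 (113-fold). H1975 was high in DHRS2 (501 CPM against 0.880), TDRD9 (198 against 0.224), PADI4 (53.7 against 0.0142), ZNF676 (52.3) and TH, tyrosine hydroxylase (46.5). It had no counts of BEX3 (at least 1110-fold lower), MYEF2 (776-fold), ADCY1 (743-fold), STK26 (525-fold) and APBA2 (412-fold).

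Whether EBC1 responded to PD-L1s differently from the adenocarcinoma lines was tested as an interaction, which sets 1 line against 3. EBC1 gave a single pair, so the spread in this test came from the other 3 lines alone. The 3 genes that passed, of 1093 with an unadjusted p under 0.05, are copies or neighbours of the U3 small nucleolar RNA, which guides ribosomal RNA cleavage. The long noncoding RNA ENSG00000262202.4_4 went from 10 to 7446 counts in EBC1 (log2 difference 7.74 ± 0.409, adjusted p = 3.26e-05) and SNORD3C from 10 to 7400 (7.43 ± 0.699, adjusted p = 5.95e-03), while SNORD3A went from 1432 to 706 (-3.22 ± 0.342, adjusted p = 0.0132). They lie on chromosome 17, from 19015313 to 19015949, 19092978 to 19093558 and 19091329 to 19092027. Near-identical copies make their counts uncertain. No protein-coding gene passed. FOSB had a difference of -1.41 ± 0.239 (adjusted p = 0.536), the smaller response being that of EBC1, and MMP7, a matrix protease, -2.10. The others named were EGFL7 (1.62), SPATA2L (1.77), PGLS (1.54), FCGBP (1.59), HIST2H3D (1.86), RP11-231C14.4 (-2.22), ZNF43 (-1.45) and ESPNL (-6.46). Without H820, 619 genes passed, without H23 11 and without H1975 3.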

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

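The tests of handling, of a different culture state, of the low markers of another line, of the share of its RNA needed and of reads shared between copies were chosen only after the result was seen; the tests of thinned counts, of leaving out H820, of the median of markers and of other splits were written down before theirs.

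Among 53 groups of 4 values tested for a value far from the others, 3 stood apart, all in H820, close to the 5% that chance gives. They were the log2 ratio of AC011513.3 (-2.49, the transcript overlapping CEACAM5), the median of histone genes (1.13) and the median of G2/M genes (1.94). The first was fixed beforehand and shows nothing, since the other 3 lines had 0 counts of AC011513.3. The lists tested were those called in these same data, so H820 standing apart in them adds no support. A difference between EBC1 and the adenocarcinoma lines passed its test for the long noncoding RNA ENSG00000262202.4_4, a neighbour of U3 copies (7.74), SNORD3C (7.43) and SNORD3A (-3.22). EBC1 gave a single pair there, so the spread came from the other 3 lines, and the count of genes ran from 3 to 619 with a line left out.

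For the count of treatment genes, 9 of the 32 splits of the 8 libraries that could be fitted gave at least the real 9 genes, with 426 as the highest other value. For gene lists 3 of the 32 splits reached the real 23, with 25 as the highest other. Both shares were large enough to count as chance under the rule written beforehand. Of the 32 splits, 24 part only 2 lines. The splits with the most calls (426 and 425 genes) set untreated against treated EBC1 and H820, where depth and treatment coincide, so these are no measure of chance. Other splits set treatment in opposite directions in 2 lines and still gave 14 genes (EBC1 and H820) and 26 genes (H23 and H820). Each split with at least 9 genes parted H820 and so carried the difference between its 2 libraries. A line that is not parted adds nothing to the fit, so the 24 splits that part 2 lines hold each contrast in mirrored form as well. The shares over 32 splits are therefore no measure of chance, and chance stays open for both counts. Among the 8 splits that, like the real one, part every line, only the real one reached 9 genes and 23 lists, with 8 genes and 20 lists as the highest of the others, but 8 splits are too few for a share under 0.125.

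The median of the immediate early genes was above 0 after PD-L1s in every line. The median of the list stayed at 0.30 once all libraries were thinned to the same total, which argues against the number of counts alone. Thinning keeps the proportions within a library, so it cannot test other differences between deep and shallow libraries. In H23 and H1975, whose pairs had similar depth, the median was 0.19 and 0.20, so uneven depth does not account for it there. The H820 pair alone does not carry the higher median, which was 0.27 without H820, where 6 members passed. Handling of the spheres when PD-L1s was added may raise the same genes, and the series holds 0 libraries of spheres handled alike without PD-L1s to test it. A response to PD-L1s and a response to handling therefore cannot be told apart here.

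Proliferation and hypoxia genes were much higher in the treated H820 library. After thinning, the G2/M median stayed at 1.86 and the hypoxia median at 0.97, which argues against the number of counts alone. Thinning cannot test other differences between the deep and the shallow H820 library. For RNA of another line, the test written beforehand took the median of marker genes of at least 50 CPM and passed the 10% that such RNA would need, at 23.9% of the level in EBC1 (2 markers, 16.0% in the untreated library) and 10.6% of that in H1975 (16 markers, 4.72% untreated), and a later test of low markers (at least 20 CPM) did not reach its bound of 5 for EBC1, with 2 of 12 EBC1, 14 of 39 H1975 and 45 of 97 H23 markers under 2% of their line. Levels of abundant genes, examined after that result, argue against it as the source of the higher levels, since the treated level would need at least 51.3% of H23 or 52.9% of EBC1 RNA and no share of H1975 RNA would reach the G2/M level, while 65 H23, 41 EBC1 and 94 H1975 genes of at least 50 CPM lay under 10% of what such a share would bring (VIM 2.27 CPM against 255 to 903 in the other lines, CDH2 and NOG 0), and the summed G2/M level of the untreated library (334 CPM) lay below those of all 3 lines (1060 to 2510). A 15 min loss of synthesis would need a half-life of 5.82 min to lower CEACAM5 as measured and 2.92 min for CYP1A1, which is consistent with 2 cultures in different states, but no half-life was measured, so a response to PD-L1s and a difference between cultures cannot be told apart.

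RP11-1212A22.4 and the U3 genes belong to families of near-identical copies. The summed counts of 7 NPIP copies changed by a mean log2 of 0.46 (SD 0.217, n = 4 lines), against 2.09 for RP11-1212A22.4 itself, whose share of the sum went from 17.1 to 39.3% in H23 and from 5.95 to 24.9% in EBC1. That sum leaves open whether the copy was transcribed more or took reads from the others. In EBC1 the summed U3 copies changed by 0.39 while SNORD3A went from 97.3 to 8.53% of the sum and SNORD3C from 0.679 to 89.4%. Placement of reads among copies is a candidate explanation, since both libraries of H1975 had about 96% of the sum on SNORD3C (96.3 and 95.9%) and both of H23 and H820 had 94.5 to 96.2% on SNORD3A.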

How the results depend on the processing

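The GC correction and the fit of H23 and H1975 only were chosen after seeing the data; the other alternatives were fixed before. The count of treatment genes (9) became 15 with library size only (10 higher, 5 lower), 98 without a filter on low counts, 3 with a minimum count of 50, 28 with H23 and H1975 only, and 5 to 20 with a line left out in turn (20 without H23, 5 without EBC1, 19 without H1975). Without the replicate block, that is without the pairing by line, 0 genes passed. Under RLE, protein-coding genes only, thinned counts, DESeq2, limma-voom and the GC correction the count stayed within 1.5 times. FOSB, FOS and RP11-1212A22.4 lost their call only without the pairing. DUSP1 and CYR61 also lost it at a minimum count of 50 and without EBC1, and CYR61 in addition with protein-coding genes only and limma-voom. HHLA2, FGB, CEACAM5 and AC011513.3 lost it at a minimum count of 50 and without the pairing. HHLA2 also lost it with thinned counts, the other 3 without EBC1 and with DESeq2, which turned FGB (-1.08) and CEACAM5 (1.07), and FGB with protein-coding genes only; without H820 none of these 4 was tested. EGR1 gained a call with library size only, without a filter, without H23, H820 or H1975, and with H23 and H1975 only. Over 27 named genes and all alternatives, 354 of 395 values kept direction and call, 25 lost the call, 14 gained it and 2 turned. The interaction count (3) became 6 with library size only, 16 without a filter, 5 with DESeq2, 0 with protein-coding genes only, and 3 to 619 with a line left out in turn (11 without H23, 619 without H820). In the contrast of EBC1 the count (13167) ran from 8691, without the treated EBC1 library, to 14283 with a library left out, and 4900 genes passed the same way against each single line. With library size only the split was 4779 higher and 8923 lower against 6791 and 6376, and for H23 12171 and 4300 against 8322 and 6618. Lists called for the treatment (23) became 0 with an estimated correlation, 0 with fry, and 12 to 24 with a line left out (12 without H820). With H23 and H1975 only, 8 were called by camera, 4 of them the same calls. Glycolysis enzymes (median -0.07, adjusted p = 0.0425), nuclear-encoded respiratory chain genes (-0.06, 0.0389) and ribosomal proteins (-0.06, 1.91e-03) were called lower there, against higher in the main comparison. The main call was kept without each line in turn by 8 lists. The 14 lists of EBC1 became 0 with an estimated correlation and 28 with fry. Genes over 2-fold within a line, at 200 counts rather than 50, were 13 against 36 in H23, 53 against 202 in EBC1, 435 against 760 in H820 and 7 against 24 in H1975, where a prior count of 1 gave 37. The effect of the count floor follows from the fewer genes described; the cause of the other changes was not tested. The untreated libraries of EBC1 and H820 were the shallowest, at 5894946 and 5559870 counts.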

Other observations

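The tests of runs of silent genes were chosen only after the result was seen; that of the genes around MET was written down before its result.

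The untreated and treated H820 spheres differed in cell cycle and xenobiotic genes, chosen here after their values were seen. MKI67, a marker of cycling cells, had 21.1 and 168 CPM, and TOP2A, the topoisomerase of dividing cells, 48.9 and 299. CYP1B1, a target of the aryl hydrocarbon receptor, had 668 and 138 CPM, and the hemoglobin gene HBA1 6.43 and 0.139. ADM, BHLHE40 and SOCS3, induced by hypoxia or cytokines, had log2 ratios of 3.04, 3.29 and 2.78 in H820. In EBC1, MIR3648 and MIR3687, which derive from the ribosomal RNA precursor, went from 692 to 3040 and from 306 to 1380 CPM. Libraries of the other lines had 2240 to 3040 CPM of MIR3648 and 608 to 1110 of MIR3687. The untreated EBC1 library was thus the lowest for both. No replicate stands behind either pair.

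Genes around MET were higher in EBC1. The 8 tested genes within 1 Mb had a median log2 of 2.58 against the other lines, above 99.8% of 15623 windows of neighbouring genes, and 6 passed higher. TES had 2.54, CAV2 3.79, CAV1 4.95, MET 4.35, CAPZA2 2.62 and ST7 2.24, whereas WNT2 (1.91) and CFTR (0.23) did not pass. The median was 0.11 in H820, -0.67 in H1975 and -2.58 in H23, where only 0.941% of windows lay below. H23 is part of the mean that EBC1 was set against, so its low levels raised the EBC1 median. TES and MET had 500 and 7200 CPM in EBC1 against 200 and 1440 in H820. WNT2 had 0.134 CPM in EBC1 and 3.98 in H23. A raised copy number of this region in EBC1 may account for its higher levels there, which counts of RNA cannot settle.

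Genes without any count in EBC1 stood next to each other. Of 12159 genes expressed in the other lines, 46 had 0 counts in both EBC1 libraries, and 2 runs of 4 neighbours were silent, with 0 such runs in the highest of 1000 shuffled gene orders. They were MAPK11, PLXNB2, DENND6B and PPP6R2 on chromosome 22 (50702142 to 50883519) and HIST1H4D, HIST1H3D, RP1-34B20.21 and HIST1H2AD on chromosome 6 (26188993 to 26199521). RP1-34B20.21 and HIST1H3D overlap on a strand and share reads. With overlapping genes counted once, 2 runs remained in EBC1, the first of 4 genes and the second of 3 without RP1-34B20.21, again with 0 in the highest shuffle. H23 had 1 such run, SERPINB4, SERPINB3 and SERPINB7 on chromosome 18 (61304493 to 61472610), and H820 and H1975 had 0. Deletion of both copies of these regions is a candidate explanation, and silencing of neighbouring genes was not tested.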
